A study of Mus musculus with 10 samples.

How the data were processed

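Expression was measured on 10 Affymetrix 1-colour arrays of 45101 probe sets, 2 arrays for each of 5 siRNA groups, taken from the labels. Per the labels' protocols, 5 ng of total RNA was amplified to cDNA, biotin-labelled and hybridised. The deposited values are intensities, 1 per probe set and array, made with RMA per the submitters' processing notes. RMA corrects the background, normalizes between arrays and summarises the probes of a set. The version of RMA, and any scaling after it, are not given in the sources used here. The values run from 5.05 to 31606.3 with array medians of 46.39 to 47.95, so they are on a linear scale, and log2 was taken before any other step. Because RMA makes array distributions alike, a change shared by most genes would not be seen. Every column of values was mapped to its sample. Most transcript levels near the bottom of the range are close to background, where RMA compresses changes.

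Probe sets were named from the platform annotation. Of the probe sets, 34958 had 1 gene symbol, 932 had several and were left out, and 9211 were not listed there and are unnamed here. Gene IDs of 34754 probe sets matched the RefSeq gene table of assembly GRCm38.p6, and no symbol changed. No genome build is given for the array, so no coordinates were used. A gene was represented by its probe set with the highest mean over all arrays, which gave 18194 genes, 9182 with 1 probe set and 9012 with more. No filter on dim genes was applied.

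One linear model over the 5 groups was fitted to log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 5 residual and 3.98 prior degrees of freedom, prior SD 0.129), because a pair of groups alone leaves few degrees of freedom. Each targeted siRNA was compared with siNonTarget, and the targeted siRNAs with each other in 6 direct contrasts. Tests were two-sided, with Benjamini-Hochberg adjustment within each contrast and a threshold of 0.05. Errors are the standard errors of this model. With 2 arrays per group no exact permutation test of a single comparison can reach 0.05. Files of figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

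Before the data were examined, 24 gene lists were fixed, covering pluripotent states, germ layers and extraembryonic lineages, fibroblast feeder cells, retinoic acid and other signalling pathways, stress responses, cell cycle and housekeeping complexes. They hold 575 entries, of which 532 matched the array (517 distinct genes); the 4 targeted genes were left out of every list. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 24 lists and 4 contrasts. Camera with an estimated correlation and fry were alternatives, and 0 of the camera calls held with the estimated correlation. The named genes follow a rule fixed at the same time: the targeted genes; the 10 largest rises and falls past the threshold whose siRNA arrays lie on the same side of both controls, or, where none passed in a direction, the 3 with the smallest p; a fixed set of pluripotency and lineage genes; up to 4 members of each called list; and the 3 largest rises and falls of each direct contrast. Clone, Gm and Rik names were skipped. Members of lists named beyond this rule (Cdx1, Lhx1, Ccnd2, Sgk1, Tfcp2l1, Bcl3, Col1a2, Twist1, Ccn2, Cdh2 and Dnmt3b) were chosen after their values were seen.

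Similarity of responses was measured as the correlation and covariance across genes of log2 changes, beside 100 simulations of unchanged groups against the same number of shared controls. Alternatives fixed in advance were a replicate block, the 2 groups of a contrast alone, quantile normalization, median centring, leaving out the dimmest 30% or 50% of genes, a trended and robust prior, the mean of a gene's probe sets, every probe set tested alone, a 2-fold minimum, and leaving out each array in turn, where the lone array of a group is assumed to vary like the other groups. Fits without the siFbxw7 and siRnf31 arrays, and without both arrays of high actin 3' to 5' difference, were added after seeing the data, as was leaving out single arrays in the list tests of the direct contrasts.

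Simulated data gave each of 18194 genes independent normal noise with the SD of the fitted model, which pools the 5 groups. The gene model was tested on these data, with 200 genes changed in each comparison. For siSocs3 against siNonTarget it recovered 36% of changes of 0.585 on the log2 scale, 88% of changes of 1 and 100% of larger ones. For siSox17 these shares were 26%, 90% and 100%, for siFbxw7 20%, 92% and 100%, and for siRnf31 34%, 94% and 100%. All 4 comparisons used the same SDs and the same changed genes. Differences between their shares therefore come from the random draw and do not measure a difference in sensitivity. False calls made up 3.7% to 8.8% of calls. On the arrays the spread differed by group: 218 genes differed at least 2-fold between replicates in siNonTarget, 208 in siFbxw7 and 13 in siSocs3. These shares may therefore not hold for the real comparisons. With no list shifted, camera called 1 of 96 list tests in simulated data. Genes were independent there, while the correlation estimated on the arrays was 0.546 in the naive pluripotency list and 0.562 in the p53 target list. The simulated share therefore does not measure false list calls on these arrays.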

Results

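The data are 10 Affymetrix mouse expression arrays of NG4 cells, a mouse embryonic stem cell line. Cells were transfected with siRNA at plating, kept in retinoic acid to start differentiation, and collected for RNA 48 h after transfection. There are 5 groups of 2 arrays. The control group, siNonTarget, received an siRNA without a target. The other 4 groups received siRNA against Sox17, Fbxw7, Socs3 or Rnf31. Sox17 is an endoderm transcription factor, Fbxw7 is the substrate-binding subunit of an SCF ubiquitin ligase, Socs3 is a feedback inhibitor of LIF and STAT3 signalling, and Rnf31 is a ubiquitin ligase of the linear ubiquitin chain complex. The series title places the experiment in work on the ubiquitin-proteasome system in embryonic stem cells, and the question is how each knockdown changes gene expression during differentiation. The median probe set intensity per array lay between 46.39 and 47.95, and 18194 genes were tested. With 2 arrays per group, the number of arrays limits the precision. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

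Replicate arrays were not always each other's closest match. Across genes, which are not independent replicates, siNonTarget replicate 1 correlated best with siFbxw7 replicate 1 (r = 0.9974, against 0.9936 with its own replicate). The array siNonTarget replicate 2 correlated best with siRnf31 replicate 2 (r = 0.9971), siFbxw7 replicate 2 with siSox17 replicate 2 (r = 0.9978), and siRnf31 replicate 1 with siSox17 replicate 1 (r = 0.9967). Both siSocs3 arrays were closest to each other (r = 0.9972). Between replicates, 218 genes differed at least 2-fold in siNonTarget, 208 in siFbxw7, 105 in siRnf31, 40 in siSox17 and 13 in siSocs3. The actin 3' to 5' log2 difference, a measure of RNA integrity, was 0.50 on siNonTarget replicate 1 and 0.60 on siFbxw7 replicate 1. On the other arrays it lay between 0.21 and 0.29.

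None of the targeted transcripts passed the test in its own group (limma, Benjamini-Hochberg). Rnf31 was −0.40 ± 0.17 on the log2 scale (SE, n = 2 arrays per group) in siRnf31 (adjusted p = 0.778), with 7.13 and 7.59 on the siRnf31 arrays against 7.91 and 7.62 on the control arrays. Fbxw7 was −0.25 ± 0.15 in siFbxw7 (adjusted p = 0.775), and its other probe set gave −0.50 ± 0.29. Fbxw7 read 9.04 and 9.28 on the siFbxw7 arrays, and 9.27 and 9.55 on the control arrays. Sox17 was 0.03 ± 0.53 in the group labelled siSox17 (adjusted p = 0.988), with 6.32 and 7.50 on those arrays and 6.37 and 7.39 on the control arrays. Without siSox17 replicate 2 this estimate was −0.56, and without siSox17 replicate 1 it was 0.62. Socs3 was 0.44 ± 0.24 in the group labelled siSocs3 (adjusted p = 0.281), with 10.66 and 10.11 on those arrays and 9.62 and 10.28 on the control arrays. Its other probe sets read 0.44 ± 0.19 and 0.47 ± 0.20 (unadjusted p = 0.047 and 0.0414), also above 0. The transcript levels therefore do not check the labels siSox17 and siSocs3. Fbxw7 and Rnf31 were lower in their own groups but did not pass, and 1 array of each group read level with a control array (9.28 against 9.27, and 7.59 against 7.62). They do not settle the labels siFbxw7 and siRnf31 either, and every direction given for the 4 groups rests on the labels.

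**Figure D1:**
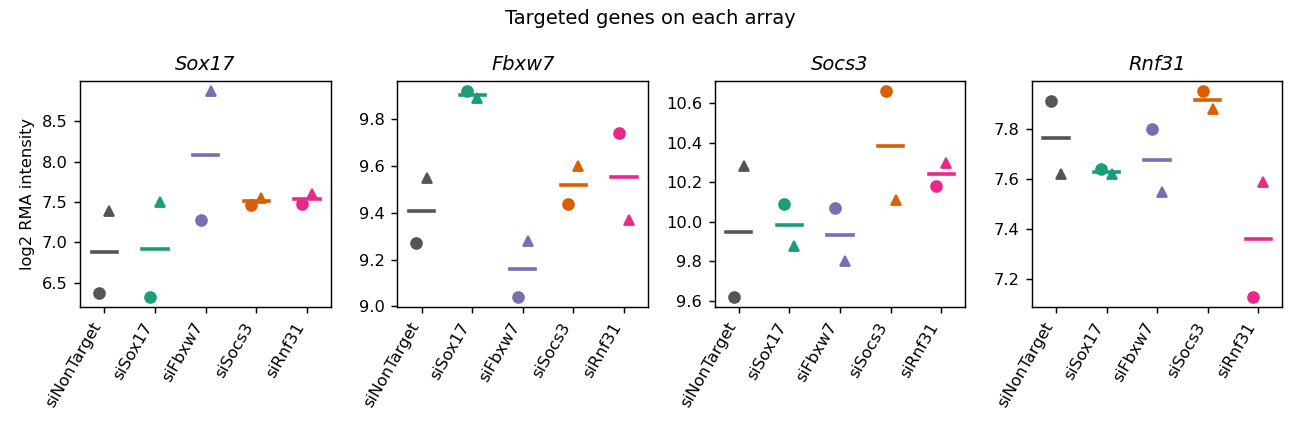
Log2 RMA intensity of each targeted gene (representative probe set) on the 10 arrays, by group; circles are replicate 1, triangles replicate 2 and bars the mean of 2 arrays. Rnf31 reads lowest on siRnf31 replicate 1 (7.13), and Socs3 reads highest on an array labelled siSocs3 (10.66).

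The arrays labelled siSocs3 differed most from the controls. Genes of the naive pluripotent state were higher and genes induced by retinoic acid were lower. Nanog rose by 1.54 ± 0.22 on the log2 scale (SE, n = 2 arrays per group, adjusted p = 0.00796), Esrrb by 1.58 ± 0.23 (0.00811), Klf4 by 1.64 ± 0.35 (0.0241) and Zfp42 by 1.01 ± 0.17 (0.0129), all transcription factors or markers of undifferentiated cells. The largest rises were in the homeobox gene Crxos (3.45 ± 0.45), Trim43a (3.40 ± 0.32), Pramel7 (3.10 ± 0.40), Bex6 (2.99 ± 0.34), Pramel6 (2.98 ± 0.50), the methyltransferase gene Bhmt (2.75 ± 0.41), the protease gene Mep1b (2.73 ± 0.37), Tcstv3 (2.69 ± 0.21), Ubtfl1 (2.59 ± 0.36) and Pramel18 (2.50 ± 0.35). The largest falls were in Aldh1a7 (−3.30 ± 0.72), Hoxb6 (−2.94 ± 0.52), the endothelin receptor gene Ednrb (−2.91 ± 0.49), the nuclear receptor gene Nr2f1 (−2.85 ± 0.57), Cyp1b1 (−2.69 ± 0.44), Zbtb16 (−2.68 ± 0.66), the growth factor gene Ptn (−2.64 ± 0.44), the neural transcription factor gene Sox1 (−2.58 ± 0.58), Hoxb5os (−2.54 ± 0.45) and Hoxb5 (−2.53 ± 0.52). Pou5f1 was 1.11 ± 0.32 and did not pass (adjusted p = 0.0645). Sox2 (−0.08 ± 0.14), Myc (−0.18 ± 0.16), Gata6 (0.02 ± 0.22), Gata4 (0.19 ± 0.29) and Fgf5 (0.07 ± 0.17) did not pass either.

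**Figure D2:**
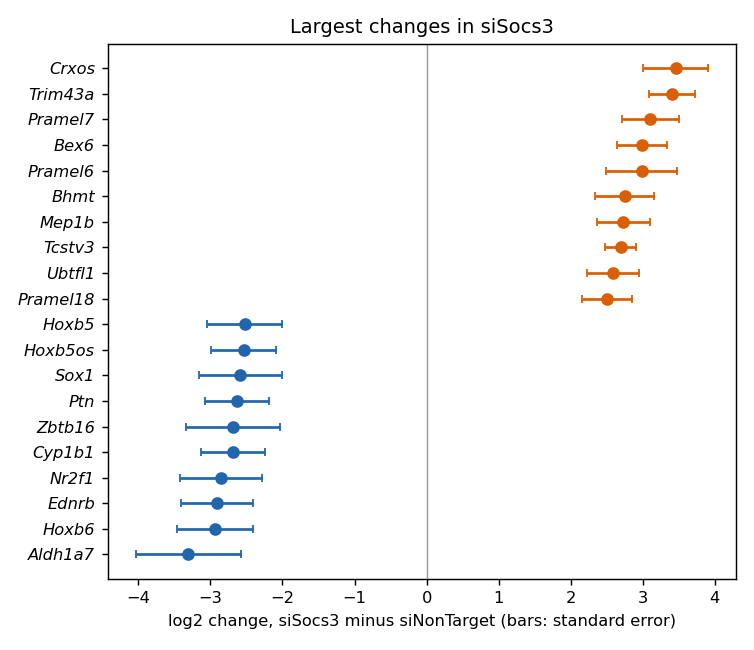
Log2 change of the 10 named genes with the largest rise and the 10 with the largest fall in the arrays labelled siSocs3, against siNonTarget; points are limma estimates from 2 arrays per group and bars are standard errors. Rises reach 3.45 (Crxos) and falls −3.30 (Aldh1a7).

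In all, 1684 of 18194 genes changed between siSocs3 and siNonTarget (limma, adjusted p under 0.05), 654 higher and 1030 lower, of which 493 changed at least 2-fold. The count depended on single arrays: it was 63 without siSocs3 replicate 1, 638 without siSocs3 replicate 2, 313 without siNonTarget replicate 1 and 1116 without siNonTarget replicate 2. Without both arrays of high actin difference, an alternative chosen after seeing the data, it was 858. Of 48 named genes that changed here, 41 lost the call without siSocs3 replicate 1, 28 without siNonTarget replicate 1, 14 without siSocs3 replicate 2 and 6 without siNonTarget replicate 2. Trim43a, Tcstv3, Bex6, Fbxo15, Prdm14, Zfp296 and Rarb, 7 genes, kept it in every alternative run for them. Bex6 and Tcstv3 had 12 alternatives and Prdm14 had 13, against 14 for the other genes, because the settings without the dimmest genes left them out.

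The gene lists fixed before the data were examined gave the same picture by group. In the naive pluripotency list, 12 of 19 measured genes rose in the arrays labelled siSocs3, and 19 rose when adjusted over the list alone. The median change was 1.09 (camera adjusted p = 1.33e-12, and adjusted p = 0.48 with an estimated correlation). Among its members, Fbxo15 rose by 1.56 ± 0.16, Prdm14 by 1.28 ± 0.14 and Klf2 by 1.09 ± 0.16. In the core pluripotency list, 5 of 15 rose, and adjusted over the list alone 11 rose and 1 fell (camera adjusted p = 6.09e-05, and adjusted p = 0.48 with an estimated correlation). Zfp296 (1.95 ± 0.17), the Nodal co-receptor gene Tdgf1 (2.06 ± 0.33), Utf1 (1.50 ± 0.24) and Dppa2 (0.94 ± 0.12) were among them. In the retinoic acid response list, 19 of 28 genes fell and 1, Cdx1, rose by 1.39; adjusted over the list alone 23 fell and 2 rose. Its median was −1.24 (camera adjusted p = 3.68e-13, and adjusted p = 0.48 with an estimated correlation). The retinoic acid receptor gene Rarb (−1.17 ± 0.13), the retinoic acid hydroxylase gene Cyp26b1 (−1.77 ± 0.24), Meis2 (−2.02 ± 0.29) and Hoxa3 (−1.21 ± 0.18) fell. In the neural ectoderm list, 11 of 23 genes fell and 12 fell adjusted over the list alone, with a median of −1.12 (camera adjusted p = 2.11e-06, and adjusted p = 0.48 with an estimated correlation). Pax6 (−2.09 ± 0.32), Zic1 (−1.81 ± 0.31), Ncam1 (−1.42 ± 0.25) and Map2 (−1.15 ± 0.17) fell. These 4 list calls held in all 20 other settings run at the preset correlation, each array left out in turn included.

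In the mesoderm and primitive streak list of the arrays labelled siSocs3, Eomes (1.52 ± 0.27), Gsc (0.83 ± 0.15) and Mixl1 (0.66 ± 0.14) rose and Lhx1 fell (−0.93), and 15 of 19 genes did not pass. Adjusted over the list alone 8 rose and 2 fell (camera adjusted p = 0.0135, adjusted p = 0.48 with an estimated correlation, and 0.068 without siNonTarget replicate 1). In the trophectoderm list, Eomes and Ascl2 (1.15 ± 0.24), 2 of 16, rose, or 9 adjusted over the list alone (camera adjusted p = 0.000439, and adjusted p = 0.48 with an estimated correlation). Its mean change of 0.70 shrank to 0.38 without siNonTarget replicate 1 (adjusted p = 0.0422). In the MYC target list, the ribosome biogenesis genes Wdr12 (0.48 ± 0.10) and Wdr43 (0.40 ± 0.10) rose, while the cyclin D2 gene Ccnd2 fell (−2.13). The count was 2 up and 1 down of 36 also when adjusted over the list alone (camera adjusted p = 0.00565, and adjusted p = 0.48 with an estimated correlation). In the Notch target list, Id2 (−1.09 ± 0.16), Hes1 (−0.59 ± 0.10) and Notch1 (−0.74 ± 0.17) fell, 3 of 16, or 4 adjusted over the list alone. That call (camera adjusted p = 0.0227) gave an adjusted p = 0.48 with an estimated correlation and 0.258 without siNonTarget replicate 2. In the STAT3 target list, Sgk1 (1.94), Klf4, Tfcp2l1 (1.37) and Bcl3 (0.78) rose, 4 of 20, or 5 up and 1 down adjusted over the list alone, and the list did not pass (camera adjusted p = 0.105; 0.0337 without siNonTarget replicate 2). In the list of fibroblast markers, which feeder cells would bring, Col1a2 (−1.45) and Twist1 (−1.40) fell and Ccn2 rose (0.95), 3 of 22 also adjusted over the list alone, with a median of 0.00 (camera adjusted p = 0.77). Camera was the list test throughout; fry, which tests whether a list's genes move one way, passed core pluripotency in siSocs3 alone among all lists and groups (adjusted p = 0.0481).

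**Figure D3:**
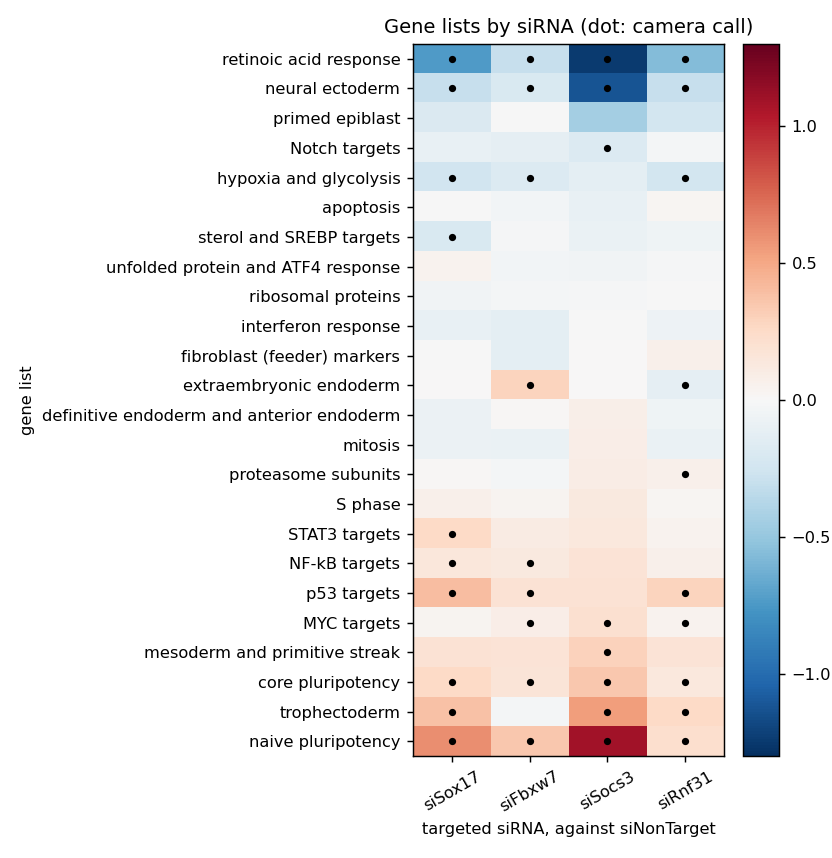
Median log2 change against siNonTarget of the 24 gene lists (vertical axis) in the 4 targeted groups (horizontal axis), red above and blue below 0; dots mark camera calls with the preset correlation. The naive pluripotency median is 1.09 and the retinoic acid median −1.24 in siSocs3.

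In the arrays labelled siSox17, 1 gene passed: Doc2a, a calcium sensor of synaptic vesicle release, fell (−1.15 ± 0.11, limma adjusted p = 0.0405). At an unadjusted p under 0.05 there were 3151 genes, where 910 are expected by chance. The count was 0 without siNonTarget replicate 2, either siSox17 array or either siSocs3 array, and 234 without either siFbxw7 array. Doc2a also lost the call without siNonTarget replicate 1 (adjusted p = 0.129) or either siRnf31 array, where 1 other gene passed each time. Without both arrays of high actin difference 16 other genes passed and Doc2a did not. A fit of siSox17 and siNonTarget alone called 254 genes, and a fit without the siFbxw7 and siRnf31 arrays, chosen after seeing the data, called 584. The rises with the smallest p did not pass: Msln (1.40 ± 0.15, adjusted p = 0.071), Matn1 (0.94 ± 0.13) and Slc15a1 (0.95 ± 0.13). Klf4 was 1.21 ± 0.35, Pou5f1 0.96 ± 0.32, Esrrb 0.93 ± 0.23, Nanog 0.77 ± 0.22 and Sox1 −1.07 ± 0.58, none past the threshold.

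By list, 10 of 24 were called in siSox17, 6 up and 4 down, although none of their genes passed over all genes. The p53 target list was up with a median of 0.40 (camera adjusted p = 5.79e-09, and adjusted p = 0.48 with an estimated correlation). Of its 22 genes, 9 rose adjusted over the list alone and 0 over all genes, and all 22 estimates were above 0. The p53 regulators and effectors Mdm2 (0.92 ± 0.24), Pmaip1 (1.15 ± 0.31) and Cdkn1a (0.62 ± 0.18) had among the smallest p. The naive pluripotency list was up with a median of 0.61 (adjusted p = 4.51e-08, and adjusted p = 0.48 with an estimated correlation), 13 of 19 adjusted over the list alone and 0 over all genes, with Fgf4 at 1.10 ± 0.29 and Klf5 at 0.96 ± 0.25. The retinoic acid response list was down with a median of −0.74 (adjusted p = 4.51e-08, and adjusted p = 0.48 with an estimated correlation), 15 down and 1 up of 28 adjusted over the list alone and 0 over all genes. Ret was −2.11 ± 0.40 and Crabp1 −2.06 ± 0.53. The neural ectoderm list was down (median −0.30, adjusted p = 0.00127, and adjusted p = 0.48 with an estimated correlation), 8 down and 1 up of 23 adjusted over the list alone and 0 over all genes. The NF-kB target list was up (median 0.15, adjusted p = 0.00294, and adjusted p = 0.48 with an estimated correlation), with 0 genes adjusted over the list alone and 0 over all genes and Icam1 at 0.88 ± 0.22. Without siNonTarget replicate 1, the control array of high actin difference, several mean changes shrank. They went from 0.57 to 0.39 (p53 targets), −0.67 to −0.46 (retinoic acid response), −0.49 to −0.41 (neural ectoderm) and 0.33 to 0.22 (NF-kB targets). The mean change of naive pluripotency grew from 0.63 to 0.72.

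The other 5 list calls in siSox17 each ended without 1 array. The trophectoderm list (up, adjusted p = 0.00159) gave 0.381 without siNonTarget replicate 1. The STAT3 target list (up, 0.00935) gave 0.0781 without siNonTarget replicate 1. The sterol and SREBP target list (down, 0.00194) gave 0.306 without siSox17 replicate 1. The core pluripotency list (up, 0.0165) gave 0.0549 without siNonTarget replicate 1 and 0.0993 without siSox17 replicate 2. The hypoxia and glycolysis list (down, 0.0316) gave 0.366 without siNonTarget replicate 1 and 0.0654 without siSox17 replicate 1. With an estimated correlation their adjusted p was 0.48, and for the sterol list adjusted p = 0.516. Adjusted over the list alone, 2 trophectoderm genes and 7 STAT3 target genes rose, 7 core pluripotency genes rose and 3 fell, and 0 passed in the sterol and hypoxia lists; over all genes 0 passed in each.

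In siFbxw7, 0 genes passed in limma, and 1174 had an unadjusted p under 0.05, where 910 are expected by chance; every other gene-level setting run also gave 0. The list of extraembryonic endoderm genes was up with a median of 0.29 (camera adjusted p = 1.42e-05, and adjusted p = 0.48 with an estimated correlation). Of its 27 genes, 6 rose adjusted over the list alone and 0 over all genes. The members with the smallest p were Foxq1 (0.90 ± 0.21), the endocytic receptor gene Cubn (1.74 ± 0.41), the collagen gene Col4a2 (0.67 ± 0.16) and the transcription factor gene Gata6 (0.80 ± 0.22). The naive pluripotency list was up with a median of 0.35 (adjusted p = 2.52e-05, and adjusted p = 0.48 with an estimated correlation), with 0 of 19 adjusted over the list alone and 0 over all genes, and Tbx3 at 0.63 ± 0.19. Both calls held in all 19 other settings run at the preset correlation, but without siFbxw7 replicate 2 the mean changes shrank from 0.35 to 0.18 (extraembryonic endoderm, adjusted p = 0.0123) and from 0.36 to 0.19 (naive pluripotency, adjusted p = 0.0284). The single genes with the smallest p were Fxyd3 (0.61 ± 0.09), Fbxl13 (0.54 ± 0.10), Tsix (0.57 ± 0.12), Lockd (−0.72 ± 0.11), Asgr1 (−0.81 ± 0.15) and Ulk2 (−0.62 ± 0.12), all at adjusted p = 0.752.

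The other 7 list calls in siFbxw7 ended without siNonTarget replicate 1, the control array of high actin difference, and also without siFbxw7 replicate 2. The retinoic acid response list (down, adjusted p = 0.0011) gave 0.651 and 0.88 without these arrays, the neural ectoderm list (down, 0.00799) 0.157 and 0.488, and the p53 target list (up, 0.00411) 0.796 and 0.287. The MYC target list (up, 0.00802) gave 0.175 and 0.135, the NF-kB target list (up, 0.0227) 0.374 and 0.617, the core pluripotency list (up, 0.0205) 0.133 and 0.159, and the hypoxia and glycolysis list (down, 0.0132) 0.498 and 0.289. With an estimated correlation the adjusted p was 0.54 for the retinoic acid list, adjusted p = 0.548 for p53 targets and 0.48 for the others. In each of these lists 0 genes passed adjusted over the list alone and 0 over all genes. On siFbxw7 replicate 1, whose actin difference was 0.60, the mean of the retinoic acid list lay 0.52 above its average over all arrays, and on replicate 2 it lay at −0.08.

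In siRnf31, 0 genes passed in limma, and 1068 had an unadjusted p under 0.05, where 910 are expected by chance; every other gene-level setting run also gave 0. The retinoic acid response list was down with a median of −0.56 (camera adjusted p = 1.58e-08, and adjusted p = 0.48 with an estimated correlation) and kept its call in all 19 other settings run at the preset correlation. Its mean change of −0.46 shrank to −0.25 without siNonTarget replicate 1, the control array of high actin difference (adjusted p = 0.00471), and to −0.27 without siRnf31 replicate 1. Of its 28 genes, 1 fell adjusted over the list alone and 0 over all genes; Rarb was −0.72 ± 0.13, the transglutaminase gene Tgm2 −0.81 ± 0.23, Hoxa3 −0.57 ± 0.18 and Cyp26b1 −0.70 ± 0.24. The single genes with the smallest p were the endoderm transcription factor gene Foxa2 (−1.24 ± 0.20), Frem1 (−1.28 ± 0.20) and Rflnb (−0.92 ± 0.14), at adjusted p = 0.698, and Trh (0.56 ± 0.13), Guca2a (0.53 ± 0.12) and Cst6 (0.53 ± 0.13), at adjusted p = 0.778.

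The other 9 list calls in siRnf31 each ended without 1 array. Without siRnf31 replicate 1 the naive pluripotency list (up, adjusted p = 0.00433) gave 0.587 and turned down, neural ectoderm (down, 0.00168) 0.131, p53 targets (up, 8.04e-06) 0.204, extraembryonic endoderm (down, 0.0227) 0.143, core pluripotency (up, 0.0412) 0.511 and MYC targets (up, 0.03) 0.233. Without siNonTarget replicate 1 the trophectoderm list (up, 0.00319) gave 0.796, hypoxia and glycolysis (down, 0.00125) 0.0714, p53 targets 0.0686, proteasome subunits (up, 0.0375) 0.366, MYC targets 0.182 and core pluripotency 0.0873. Without siNonTarget replicate 2 the naive pluripotency list gave 0.198, extraembryonic endoderm 0.169, core pluripotency 0.118 and MYC targets 0.0506. Proteasome subunits gave 0.234 without siRnf31 replicate 2 and 0.074 after quantile normalization, and core pluripotency 0.0505 without siSocs3 replicate 2. With an estimated correlation the adjusted p was 0.54 for naive pluripotency, adjusted p = 0.516 for extraembryonic endoderm, 0.533 for MYC targets and 0.48 for the others. Adjusted over the list alone 1 gene fell in the extraembryonic endoderm list and 1 in the neural ectoderm list, and 0 passed in the others; over all genes 0 passed in each. The mean of the naive pluripotency list lay at 0.04 on siRnf31 replicate 1 and at −0.54 on replicate 2, relative to the average over all arrays.

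The remaining 9 lists were called in none of the 4 groups against siNonTarget, with camera adjusted p from 0.12 to 0.89. They held genes of the primed epiblast, definitive and anterior endoderm, fibroblasts, the interferon response, the unfolded protein and ATF4 response, S phase, mitosis, ribosomal proteins and apoptosis. Mitosis was called in direct comparisons of siSocs3 with the other targeted groups, given below. In the arrays labelled siSocs3 the primed epiblast list held 4 genes that fell and 1 that rose of 16 (4 and 2 adjusted over the list alone), among them Cdh2 (−1.70) and Dnmt3b (0.84).

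**Figure D4:**
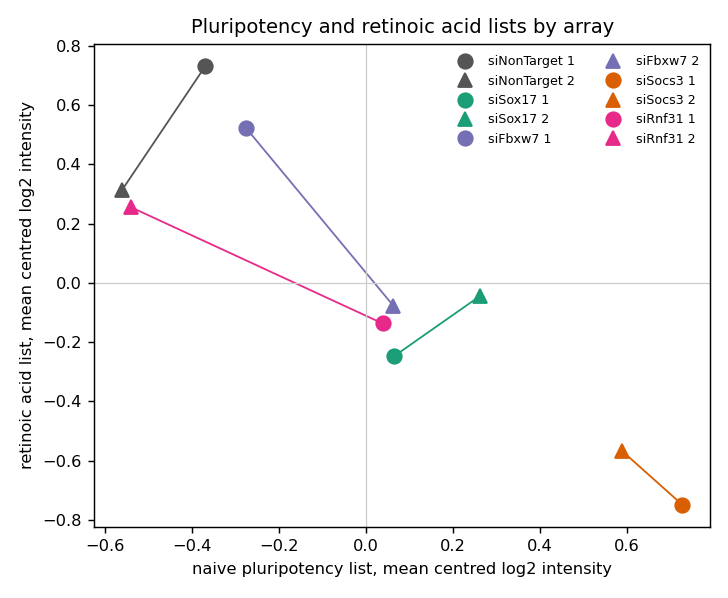
Mean of the naive pluripotency list (horizontal) and of the retinoic acid response list (vertical) on each of the 10 arrays, in log2 units relative to the average over all arrays; lines join the 2 replicates of a group. The siSocs3 arrays lie at 0.73 and 0.59 on the horizontal axis, and the siRnf31 replicates at 0.04 and −0.54.

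Direct tests compared the targeted siRNAs with each other. The arrays labelled siSocs3 differed from those labelled siSox17 in 474 genes (298 higher, 176 lower), from siFbxw7 in 638 (381 higher in siSocs3, 257 lower) and from siRnf31 in 387 (273 higher, 114 lower). Pramel6 was 3.48 ± 0.50 higher than in siSox17, 3.04 ± 0.50 higher than in siRnf31, and −3.58 ± 0.50 in siFbxw7 relative to siSocs3. Ubtfl1 (3.56 ± 0.36) and Bex6 (3.42 ± 0.34) were also higher than in siSox17, and the transcription factor gene Sp8 (−2.36 ± 0.34), Gap43 (−1.82 ± 0.25) and Csn3 (−1.75 ± 0.25) lower. Relative to siSocs3, siFbxw7 had more Hoxb6 (2.46 ± 0.52), Sp8 (2.26 ± 0.34) and Gpr50 (2.16 ± 0.45) and less Crxos (−3.52 ± 0.45) and Trim43a (−3.29 ± 0.32). Against siRnf31, Bex6 (2.85 ± 0.34) and Tcstv3 (2.77 ± 0.21) were higher in siSocs3, and Hoxc8 (−2.17 ± 0.29), Zic1 (−2.00 ± 0.31) and Crabp2 (−1.84 ± 0.38) lower. Without siSocs3 replicate 1 the counts were 77, 81 and 22, without siSocs3 replicate 2 they were 227, 292 and 160, without siSox17 replicate 1 they were 140, 407 and 222, and without siSox17 replicate 2 they were 104, 407 and 222. The siFbxw7 count was 181 without siFbxw7 replicate 1, and the siRnf31 count was 141 without siRnf31 replicate 1 and 122 without siRnf31 replicate 2. Without both arrays of high actin difference the counts were 740, 218 and 677.

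In list tests chosen after seeing the data, camera called 7 lists between siSocs3 and siSox17, 8 against siFbxw7 and 8 against siRnf31. With an estimated correlation it called 0, and some calls were lost without single arrays. Mitosis was higher in siSocs3 than in siSox17, siFbxw7 and siRnf31 (camera adjusted p = 0.00387, 0.00452 and 0.00596). Core pluripotency was also called higher and neural ectoderm lower than in each, and p53 targets lower than in siSox17 (0.000114). Among siSox17, siFbxw7 and siRnf31, limma called 0 genes in each direct comparison. At an unadjusted p under 0.05 there were 1017 genes between siFbxw7 and siSox17, 1397 between siRnf31 and siSox17 and 945 between siFbxw7 and siRnf31, where 910 are expected. The count between siRnf31 and siSox17 was 2 without either siNonTarget array, and the other gene-level settings gave 0. A list test of these contrasts was chosen after seeing the data; camera called 7 lists between siFbxw7 and siSox17, 5 between siRnf31 and siSox17 and 4 between siFbxw7 and siRnf31, and 0 in each with an estimated correlation (adjusted p = 0.55 or higher). Leaving out each array of the groups in turn, also chosen after seeing the data, kept 3, 0 and 1 of these calls. Kept in siFbxw7 relative to siSox17 were lower p53 targets (median −0.24, adjusted p = 9.54e-08), trophectoderm (−0.44, 6.07e-05) and STAT3 targets (−0.17, 0.00484). The mean change of p53 targets shrank from −0.36 to −0.22 without siSox17 replicate 1 or siFbxw7 replicate 1, and that of trophectoderm from −0.41 to −0.20 without siFbxw7 replicate 1. Kept in siFbxw7 relative to siRnf31 was higher extraembryonic endoderm (median 0.55, adjusted p = 1.31e-11). Lost between siFbxw7 and siSox17 were lower naive pluripotency (adjusted p = 0.000316, and 0.263 without siFbxw7 replicate 1 or 0.105 without siSox17 replicate 2), higher retinoic acid response (1.57e-05, and 0.456 without siFbxw7 replicate 1), higher extraembryonic endoderm (0.000114, and 0.213 without siFbxw7 replicate 2) and higher sterol targets (0.000103, and 0.324 without siSox17 replicate 1). Lost between siRnf31 and siSox17, all without siRnf31 replicate 2 unless stated, were lower naive pluripotency (1.56e-05, then 0.194), p53 targets (0.000808, then 0.641, or 0.354 without siSox17 replicate 1), STAT3 targets (0.0323, then 0.381, or 0.105 without siSox17 replicate 1) and extraembryonic endoderm (0.00389, and 0.219 without siRnf31 replicate 1), and higher sterol targets (0.0333, then 0.791, or 0.822 and turned down without siSox17 replicate 1). Lost between siFbxw7 and siRnf31 without siFbxw7 replicate 1 were higher retinoic acid response (0.0283, then 0.22 and turned down, or 0.925 without siRnf31 replicate 1), lower trophectoderm (0.0111, then 0.413, or 0.124 without siRnf31 replicate 1) and lower proteasome subunits (0.00766, then 0.157, or 0.0814 without siRnf31 replicate 2).

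The responses of the 4 groups were compared across genes, which are not independent replicates. All comparisons share the same control arrays. Unchanged groups simulated with shared controls gave r = 0.50 and a covariance of 0.0166. That simulation drew the controls too, from the spread pooled over the 5 groups. The root mean square SD between replicates was 0.212 in siNonTarget, 0.211 in siFbxw7, 0.183 in siRnf31, 0.152 in siSox17 and 0.14 in siSocs3. The simulated covariance may therefore be too low for these controls, and the excesses below too large. The observed r was 0.755 between siSox17 and siFbxw7, 0.707 between siSox17 and siRnf31, 0.646 between siSocs3 and siRnf31, 0.611 between siSox17 and siSocs3, 0.547 between siFbxw7 and siRnf31, and 0.514 between siFbxw7 and siSocs3. The covariance exceeded the simulated one by 0.0611 for siSox17 with siSocs3, 0.0387 for siSocs3 with siRnf31, 0.0323 for siSox17 with siFbxw7, 0.0303 for siSox17 with siRnf31, 0.0263 for siFbxw7 with siSocs3 and 0.00727 for siFbxw7 with siRnf31. The responses were not measured against separate control arrays, so part of the excess may come from the shared controls. No called gene could be shared in the higher direction, because siSox17, siFbxw7 and siRnf31 had 0 genes called higher. In the lower direction Doc2a was called in both siSox17 and siSocs3, tested against the same control arrays. Of the 1030 genes lower in siSocs3, 91.6% (siFbxw7) to 94.7% (siRnf31) also lay below the controls in the other groups. Of the 654 higher genes, 66.7% (siFbxw7) to 80.4% (siRnf31) also lay above. The shared controls raise these shares, so they do not measure a common response alone.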

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

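The tests of explanations in this part were chosen after the results were seen, and leaving out single arrays was planned for lists compared with siNonTarget only. Among the 9211 probe sets without a gene name, which the comparisons by gene do not use, 61 changed in the arrays labelled siSocs3 against siNonTarget (43 higher, 18 lower, limma adjusted over these probe sets), a signal in data outside the main measurement. In siSox17, siFbxw7 and siRnf31 limma called 0 of them, with 623, 413 and 462 at an unadjusted p under 0.05, and 0 of 51 Affymetrix control probe sets changed in any group.

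Replicate arrays of siFbxw7 and siRnf31 resembled other groups more than each other. The labels do not say whether arrays were processed in batches, so a batch shared across groups was not tested. For siFbxw7 replicate 2, a siSox17 array under a wrong label is argued against by Fbxw7, which lay more than the bound of 3 SD below the siSox17 arrays in both of its probe sets (−3.24 SD in the nearer). Part of that gap comes from siSox17, where Fbxw7 stood 0.50 ± 0.16 and 0.71 ± 0.29 above siNonTarget in these probe sets. The gap therefore does not measure a fall of Fbxw7 on siFbxw7 replicate 2. Wrong labels stay open for siFbxw7 replicate 1 as a control array (Fbxw7 at −1.33 SD), siRnf31 replicate 1 as a siSox17 array (Rnf31 at −2.42 SD) and siRnf31 replicate 2 as a control array (−0.836 SD), because these levels fall short of the bound. Replicate differences of siFbxw7 and siNonTarget, the groups with 1 high actin array each, correlated across genes at r = 0.421. The other 9 pairs of groups gave at most 0.0918. A control array labelled siFbxw7 replicate 1 would give this r only by sharing what set siNonTarget replicate 1 apart from replicate 2. A wrong label alone does not predict it. RNA quality and a wrong label could hold together for siFbxw7 replicate 1, so the r does not settle its label. For the siRnf31 arrays RNA quality is argued against by an actin log2 difference between replicates of 0.0228, and unequal knockdown there was not tested.

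In the arrays labelled siSocs3 the naive pluripotency list was higher and the retinoic acid list lower than in siNonTarget. RNA quality of siNonTarget replicate 1 is argued against as the whole cause: without both arrays of high actin difference the mean changes were 1.22 and −0.97, against 1.12 and −1.18 with them, and camera still called both lists (adjusted p = 1.11e-12 and 2.76e-12), although with all arrays each had an adjusted p = 0.48 with an estimated correlation. Fewer fibroblast feeder cells are argued against as the whole source of the retinoic acid fall. The fibroblast list had a median of 0.00241 ± 0.0999 (SE of the median) over 22 genes, against −1.24 in the retinoic acid list. That SE is taken across genes of the same arrays and does not measure spread between arrays. The fibroblast list mean lay at −0.296 and 0.291 on the control arrays, with the siSocs3 arrays between them (−0.105 and 0.0817). Single markers went both ways: Col1a2 and Twist1 fell and Ccn2 rose. Whether less Socs3 is behind the pattern cannot be told apart from other effects of the transfection, because the Socs3 transcript stood at 0.435 and did not pass in either direction. A biological difference between the groups remains a hypothesis.

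In all 4 targeted groups the naive pluripotency list was called higher and the retinoic acid list lower than in siNonTarget (adjusted p from 0.48 to 0.54 with an estimated correlation), but the naive list in siRnf31 lost its call without siRnf31 replicate 1 (turned down, adjusted p = 0.587) or siNonTarget replicate 2 (0.198), and the retinoic acid list in siFbxw7 without siNonTarget replicate 1 (0.651) or siFbxw7 replicate 2 (0.88). For siSocs3, chance spread of the 2 control arrays is argued against as the whole cause by comparisons that do not use them: at least 387 genes differed between siSocs3 and each other targeted group, and both lists were called in the same directions, also without each array of the groups compared (adjusted p from 0.55 to 0.608 with an estimated correlation). For siSox17 such comparisons rest on single arrays: naive pluripotency was higher than in siFbxw7 (adjusted p = 0.000316, and 0.263 without siFbxw7 replicate 1) and siRnf31 (1.56e-05, and 0.194 without siRnf31 replicate 2), the retinoic acid list was lower than in siFbxw7 (1.57e-05, and 0.456 without siFbxw7 replicate 1) but not called against siRnf31 (0.103), all had adjusted p from 0.606 to 0.82 with an estimated correlation, and limma called 0 genes (1017 and 1397 at an unadjusted p under 0.05). The covariance of responses was at most 4.68 times the simulated one (siSox17 with siSocs3), and 2.94 times among siSox17, siFbxw7 and siRnf31, under the 6.61 needed if all genes moved together. That bound treats all genes as 1 observation, so falling short of it decides nothing. For siSox17, siFbxw7 and siRnf31 the comparisons made here cannot tell chance spread of the controls apart from an effect of the siRNAs.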

How the results depend on the processing

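Fits without the siFbxw7 and siRnf31 arrays and without both arrays of high actin difference were chosen after seeing the data. With the replicate block the siSox17 count went from 1 to 0 and the siSocs3 count from 1684 to 1517; it changed no other count of genes or lists by over 1.5 times, and replicate numbers did not pair the arrays (replicate differences correlated above 0.1 in 1 of 10 pairs of groups, from −0.26 to 0.421). The siSox17 count was also 0 without the dimmest 50% of genes, with the trended and robust prior and over every probe set. It was 3 with the mean of probe sets and 16 without both high actin arrays, and the cause was not tested. It was 254 with the 2 groups alone and 584 without the siFbxw7 and siRnf31 arrays. Both of these fits kept all siSox17 and siNonTarget arrays, so the estimated changes stayed the same and only their error could differ. The root mean square SD between replicates was 0.211 in siFbxw7 and 0.183 in siRnf31. It was 0.152 in siSox17, 0.14 in siSocs3 and 0.212 in siNonTarget. The main count of 1 therefore depends on the error pooled over the 5 groups. At a 2-fold minimum the counts were 493 for siSocs3 against siNonTarget, 175 against siSox17, 250 against siFbxw7 and 173 against siRnf31. With the 2 groups alone siSocs3 differed from siSox17 in 881 genes and from siFbxw7 in 307, and without the dimmest 50% from siRnf31 in 245. Without both high actin arrays these counts were 858, 740, 218 and 677. For siSocs3 against siSox17 (740) and siRnf31 (677) all arrays compared were kept, so only the error could differ. For the other counts without the high actin arrays the cause was not tested. With an estimated correlation 0 lists were called in each group, and with fry 0, 0, 1 and 0 in siSox17, siFbxw7, siSocs3 and siRnf31. Leaving out each array in turn gave 0 to 234 genes in siSox17, 0 to 0 in siFbxw7, 63 to 2074 in siSocs3 and 0 to 0 in siRnf31. It gave 77 to 521 between siSocs3 and siSox17, 81 to 898 between siFbxw7 and siSocs3, 22 to 552 between siSocs3 and siRnf31, 0 to 2 between siRnf31 and siSox17, and 0 in the other direct contrasts. Lists called ranged from 7 to 11 in siSox17, 2 to 11 in siFbxw7, 7 to 11 in siSocs3 and 5 to 11 in siRnf31. Target estimates ranged from −0.56 to 0.62 for Sox17, −0.38 to −0.11 for Fbxw7, 0.10 to 0.77 for Socs3 and −0.63 to −0.17 for Rnf31. Of 904 alternatives of the 67 named gene results past the threshold, 744 kept the call, 160 lost it and 0 turned direction; of 2337 for the other named genes, 52 passed. The largest rises and falls were picked with both siRNA arrays on the same side of both arrays compared, so leaving out 1 array could not turn them. Alternatives that change only the error could turn no gene. The lack of turned directions is therefore largely fixed by the selection. Dim probe sets near background limit what can be seen of genes with low signal.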

Other observations

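The lists in this part were put together after the results were seen. Genes known from 2-cell embryos were higher in the arrays labelled siSocs3: 15 of 19 measured genes rose and 0 fell, or 16 adjusted over the list alone, with a median of 2.02 (camera adjusted p = 1.41e-16, and adjusted p = 0.289 with an estimated correlation). Because the list was drawn up after several of its members had been seen among the largest rises, its test is not independent evidence. The same holds for the Pramel family list below, which includes Pramel6, Pramel7 and Pramel18. Besides Trim43a, Tcstv3 and Ubtfl1, the genes Tcstv1 (2.34 ± 0.24), Zfp352 (2.31 ± 0.31), Usp17la (2.02 ± 0.26) and Tdpoz1 (1.72 ± 0.24) rose. In siSox17, siFbxw7 and siRnf31 limma called 0 of the 19, with medians of −0.42, −0.18 and 0.02 (camera adjusted p = 0.0574, 0.0702 and 0.678). Of 12 Pramel family genes, 5 rose in siSocs3, and 5 adjusted over the list alone (camera adjusted p = 8.37e-05, and adjusted p = 0.289 with an estimated correlation), Pramel13 by 1.24 ± 0.26 and Pramel12 by 0.93 ± 0.20 among them; probe sets of such related genes can cross-hybridise. Of 22 germline genes, 6 rose and 1 fell, or 9 in all adjusted over the list alone, including Tex19.1 (1.58 ± 0.13), Dazl (1.17 ± 0.22) and Stra8 (−0.48 ± 0.11), a gene induced by retinoic acid, and the list did not pass (camera adjusted p = 0.129).

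Of 22 HOX genes outside the retinoic acid list, 5 fell in the arrays labelled siSocs3, or 7 passed adjusted over the list alone: Hoxc8 (−2.42 ± 0.29), Hoxc4 (−2.18 ± 0.45), Hoxc5 (−2.13 ± 0.49), Hoxc9 (−0.86 ± 0.17) and Hoxd3 (−0.65 ± 0.14); the list did not pass (camera adjusted p = 0.155). Among 27 ephrin and axon guidance genes, 6 fell and 1 rose, or 8 passed adjusted over the list alone (camera adjusted p = 0.0998), with Plxna2 at −2.19 ± 0.35, Slit2 at −1.96 ± 0.43 and the netrin receptor gene Dcc at 0.78 ± 0.13. In siFbxw7 that list was down with 0 genes past the threshold (camera adjusted p = 0.0361, and adjusted p = 0.289 with an estimated correlation). Among 13 genes of the neural crest and enteric nervous system, Ednrb, Zeb2 (−1.69 ± 0.27) and Gfra1 (−1.35 ± 0.33) fell and Erbb3 rose (1.20 ± 0.25), or 7 passed adjusted over the list alone, and the list did not pass (camera adjusted p = 0.29). Among 20 LIF and cytokine receptor genes, Stat6 (0.82 ± 0.14) and Csf3r (0.76 ± 0.10) rose and Ghr fell (−0.84 ± 0.19), or 6 passed adjusted over the list alone, and the list did not pass (camera adjusted p = 0.678).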
